A study of Mus musculus with 6 samples.

How the data were processed

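RNA of mouse natural killer (NK) cells was measured with a NanoString nCounter panel, which counts fluorescent barcodes hybridised to each transcript without amplification. The 6 libraries fell into 3 groups of 2, taken from the expansion method and the treatment in the labels. Per the labels' protocols, NK cells of C57BL/6 mice were expanded for 12 days in 10 ng/mL of an IL-15 and IL-15 receptor alpha conjugate, with or without feeder cells irradiated at 100 Gy. The antibody was present for 4 h, after which the NK cells were purified again before RNA extraction. The labels conflict in 2 places. The control libraries carry no treatment in their labels although the design text names an isotype control antibody, so they are called untreated here with that reservation. If the controls had no antibody incubation, the antibody's effect cannot be told apart from that of the 4 h step itself. The labels also describe quantitative PCR, whereas the deposited files hold NanoString probes and controls.

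The deposited value table gave log2 values of 532 probes, of which 498 were endogenous genes, 20 were housekeeping genes and 14 were spike-in controls. The authors' scaling was read from the values, since no header or label states it: the mean log2 value of the 20 housekeeping probes was 9.22 in every library. Per the submitters' processing notes limma was used, with no version or role given. The smallest step between values of a library gave back whole counts for 100.0% of the values, within a tolerance of 0.01 of a whole number. The recovered totals ran from 299485 to 441185 counts per library, and the 8 negative controls averaged between 4.25 and 6.13 counts. A further 18 columns of values per sample, and 12 rows of quality values, were named by instrument lane and were not used, because lanes could not be assigned to samples by name. The authors' deposited table of 1 comparison gave a log2 fold change, a test score, a p-value and a q-value for 498 genes between groups named only by number.

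Differences were tested with limma 3.58.1 in R 4.3.3 on the deposited log2 values, with no pseudocount. A linear model of the 3 groups was fitted over all 6 libraries, with a variance trend and robust moderation, and p-values were adjusted by Benjamini-Hochberg at 0.05. Probes with at least 20 recovered counts in at least 2 libraries were tested, which kept 430 probes, housekeeping genes among them, and left out 88. The design fixed before the data were examined assumed raw counts, a count model and scaling by trimmed mean of M values (TMM). The deposited values assignable to samples were on a log2 scale, and limma on these housekeeping-scaled values was used instead. The planned count-model fits were not run on the recovered counts either. Libraries of a group are separate samples in the labels, but nothing says that they came from separate animals, so the p-values measure the spread between these samples, which may be technical. Fold changes are given as log2 values ± the standard error of the fit, with n = 2 libraries per group.

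The genes to be named were set by a rule fixed before the data were examined. It took the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap and whose mean reached 50 counts in the higher group. Where fewer than 10 passed, the smallest p-values filled the number. Havcr2, and up to 4 members of each list with the largest absolute log2 fold change, were added. Other genes are named as chosen after their values were seen. Some genes that the rule selects are not reported here. The 19 gene lists, also fixed beforehand, held 374 symbols, of which 234 were in the value table. Lists with at least 3 tested members were tested with camera of limma, at a preset correlation of 0.01 and again with an estimated correlation.

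The script was tested on simulated data with the real probe means, library totals and spread. In 20 simulations of the anti-TIM-3 comparison with 200 of 430 probes changed, limma called 19.8% of probes changed 1.5-fold, 58.8% of those changed 2-fold, 92.3% of those changed 4-fold and 98.4% of those changed 8-fold. Of all those calls, 3.23% were of unchanged probes. The housekeeping probes were never changed in these simulations, rises and falls were equal in number, and errors were independent between probes. These rates therefore leave out any error of the housekeeping scale. In 20 simulations of the anti-TIM-3 comparison over 430 probes, camera called 20 of 20 shifted lists and 2 of 320 unshifted lists. These simulated probes varied independently of each other. The result does not cover lists whose members vary together, such as the NF-kB pathway list, with an estimated correlation of 0.526.

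Scaling by TMM, the scaling planned for the main fit, was run as an alternative on log2 CPM with a prior count of 2. Further alternatives fixed beforehand were scaling by positive controls and by total count, other count filters and subtraction of the negative control mean. A fit of only the 4 libraries compared, the title number as a block, and leaving out each library were also fixed beforehand. Median-of-ratios scaling, voom on the recovered counts, and limma without trend or robust moderation were chosen after seeing the data. So was the count of calls that passed in the same direction on the housekeeping scale and on all 4 other scales. Probes for Ly49 receptors (Klra genes), Ifitm1 and Ifitm2, and class I H2 genes target near-identical family members, so signal may be shared between them. Figures were drawn with matplotlib 3.10.9.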

Results

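NK cells are innate lymphocytes that kill target cells and secrete cytokines, and TIM-3, encoded by Havcr2, is a receptor on their surface that is a target of blocking antibodies. The data were transcript levels in 6 libraries of expanded mouse NK cells. Of these, 2 were expanded with IL-15 alone, 2 with IL-15 and irradiated AgN2a-4P feeder cells, and 2 with IL-15 and feeder cells followed by anti-TIM-3 antibody. AgN2a-4P is a mouse neuroblastoma line engineered to carry CD80, CD86, CD54 and CD137L. The recovered counts totalled 422455 and 441185 in the IL-15 libraries, 379767 and 359824 in the untreated feeder libraries, and 409626 and 299485 in the anti-TIM-3 libraries. Libraries of a group correlated across genes at r between 0.959 and 0.972, and differed by far more than counting noise, with a chi-square of at least 37.9 per degree of freedom. IL-15 and untreated feeder libraries did not separate by group: IL-15 replicate 3 correlated with untreated feeder replicate 2 at r = 0.975, against 0.959 between the 2 IL-15 libraries.

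The anti-TIM-3 comparison asks what differed after the antibody step in NK cells expanded on feeder cells. If the controls had no isotype antibody, any effect of the incubation itself is part of these differences. Havcr2, the gene of the antibody's target, fell by 4.41 ± 0.62 on the log2 scale in the anti-TIM-3 libraries (adjusted p = 0.00884, limma with Benjamini-Hochberg). Its normalised count was 87.9 and 24.3 in the anti-TIM-3 libraries, 717 and 1343 in the untreated feeder libraries, and 682 and 538 in the IL-15 libraries. The antibody binds the protein, so the transcript checks no label. The call on Havcr2 was kept on all 4 other scales, and ended without untreated feeder replicate 3, where the log2 fold change was -3.96 and the limma adjusted p was 0.0680.

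**Figure D1:**
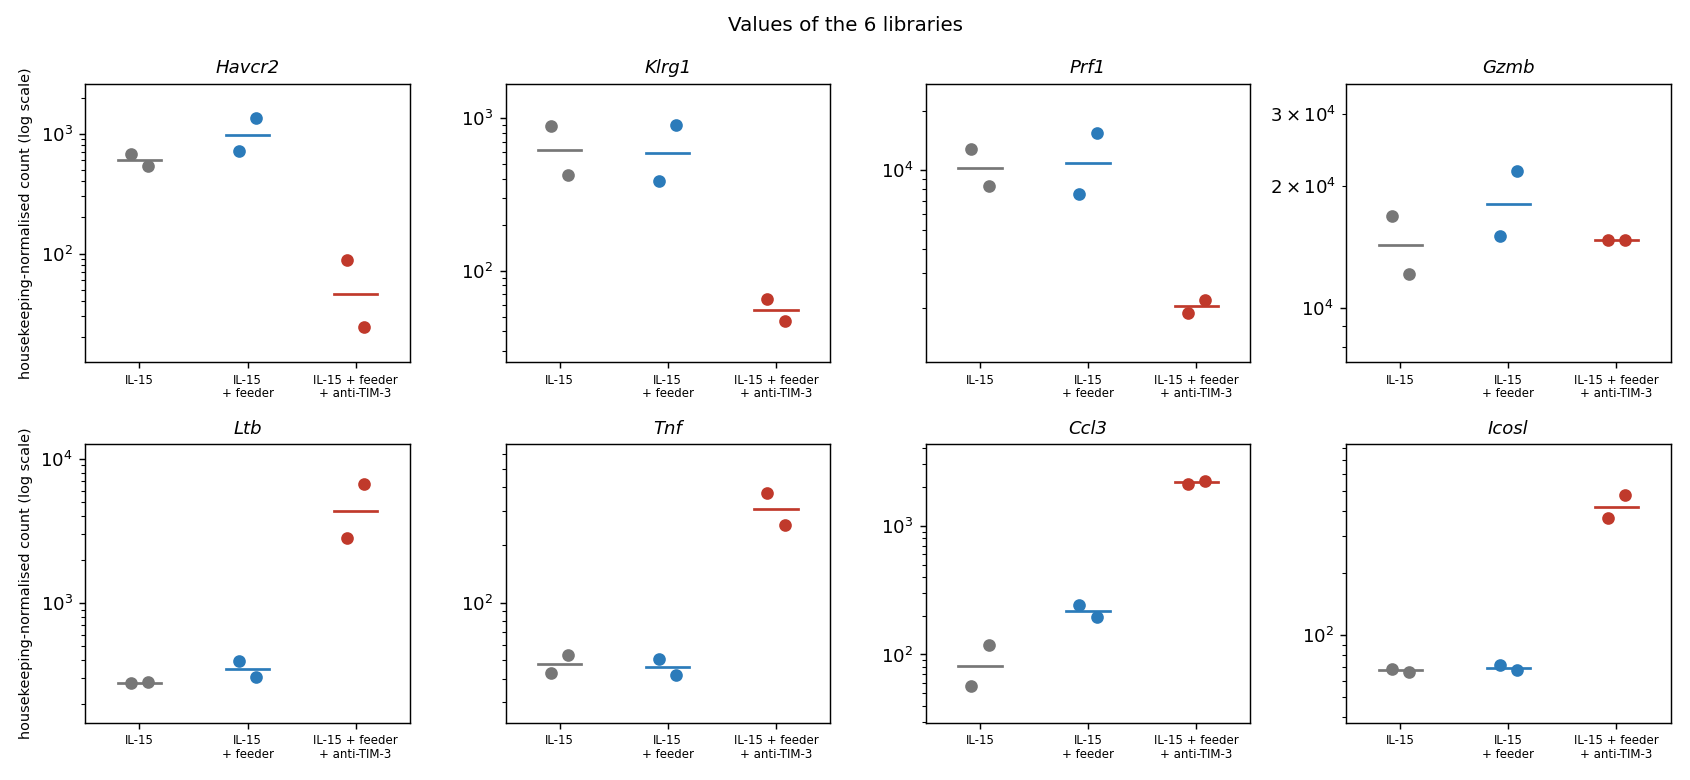
Housekeeping-normalised counts of 8 genes on log axes, with each library as a point and each group's geometric mean as a line (2 libraries per group). Havcr2, Klrg1 and Prf1 were lower in both anti-TIM-3 libraries than in the other 4 libraries, and Ltb, Tnf, Ccl3 and Icosl were higher, while Gzmb overlapped.

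Genes of secreted cytokines and chemokines led the rises under anti-TIM-3. Ltb, the lymphotoxin beta chain, rose by 3.65 ± 0.40 on the log2 scale, from a normalised count of 350 to 4778. The chemokine genes Ccl1 (3.38 ± 0.77) and Ccl3 (3.31 ± 0.36), the growth factor gene Csf2 (2.82 ± 0.48) and Tnf (2.75 ± 0.31) rose as well. The other leading rises were the invariant chain gene Cd74 (3.13 ± 0.90), the NK receptor genes Klra4 (2.71 ± 0.76) and Klrc2 (2.69 ± 0.62), Tnfsf8, the ligand of CD30 (2.70 ± 0.26), and Lta, encoding lymphotoxin alpha (2.66 ± 0.64). None of these calls passed without untreated feeder replicate 3. The Ccl1 call also ended without either IL-15 library (limma adjusted p = 0.0997 and 0.0980), and those of Cd74, Klra4 and Lta without anti-TIM-3 replicate 1 (limma adjusted p = 0.0922, 0.0643 and 0.0747). Without anti-TIM-3 replicate 2 those of Ccl1, Cd74, Klra4, Klrc2 and Lta ended (limma adjusted p of 0.0532 to 0.142), and without untreated feeder replicate 2 those of Klra4 and Klrc2 (limma adjusted p = 0.144 and 0.0562). Cd74 was at 1.92 without untreated feeder replicate 3.

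The largest falls were deeper than the largest rises. Ifitm1, encoding an interferon-induced membrane protein, fell by 5.76 ± 1.08 on the log2 scale, and Ifitm2 fell by 4.42 ± 0.78. Their recovered counts differed widely between the anti-TIM-3 libraries, at 254 and 13 for Ifitm1 and 831 and 86 for Ifitm2, and without anti-TIM-3 replicate 2 the log2 fold changes were -3.93 and -3.10. Both calls ended without any 1 of the IL-15 or untreated feeder libraries (limma adjusted p of 0.0566 to 0.0893 for Ifitm1 and 0.0553 to 0.0770 for Ifitm2), and that of Ifitm1 on the positive control scale (limma adjusted p = 0.178). The serine protease genes Ctsg (-5.63 ± 0.76) and Cma1 (-5.21 ± 1.05), Cd55, encoding a complement regulator (-5.05 ± 0.76), and Vegfa, an angiogenic factor gene (-4.01 ± 0.35), fell too. Klrg1, an inhibitory receptor gene (-3.42 ± 0.51), Klra2, of the Ly49 family (-3.27 ± 0.67), and Spp1, encoding osteopontin (-3.21 ± 0.70), completed the 10 largest with Havcr2. Spp1 remained abundant, at a normalised count of 2945 in the anti-TIM-3 libraries against 28134. In the anti-TIM-3 libraries Ctsg had 16 and 4 recovered counts, Cma1 6 and 1, and Klra2 6 and 4, at or near the level of the negative controls, so the sizes and ranks of these 3 falls are poorly determined. Without anti-TIM-3 replicate 2 the calls on Cma1, Klra2 and Spp1 ended (limma adjusted p = 0.0677, 0.0547 and 0.0882), and without untreated feeder replicate 2 that on Spp1 (limma adjusted p = 0.0511).

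In all, 166 of 430 probes passed the threshold in limma with Benjamini-Hochberg adjustment, of which 135 rose and 31 fell, and the median log2 fold change of all tested probes was 0.47. Eef1g, among the housekeeping probes that set the scale, was itself among the falls (-0.77). The split depended on the scale. With TMM, the planned scaling, 44 rose and 51 fell (median -0.06). The numbers were 32 and 37 with positive controls (-0.04), 63 and 37 with total count (0.20), and 53 and 49 with median of ratios (-0.03). On all of these scales 26 rises and 26 falls passed. Every call ended without untreated feeder replicate 3, and most ended without untreated feeder replicate 2 or anti-TIM-3 replicate 2. The median log2 fold change was then 0.51, 0.43 and 0.39. Each of these fits leaves 1 library in a group and fewer total degrees of freedom (median 4.85 without untreated feeder replicate 3, against 6.18). The calls thus need these libraries, but their loss does not show that the effects rest on 1 library.

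**Figure D2:**
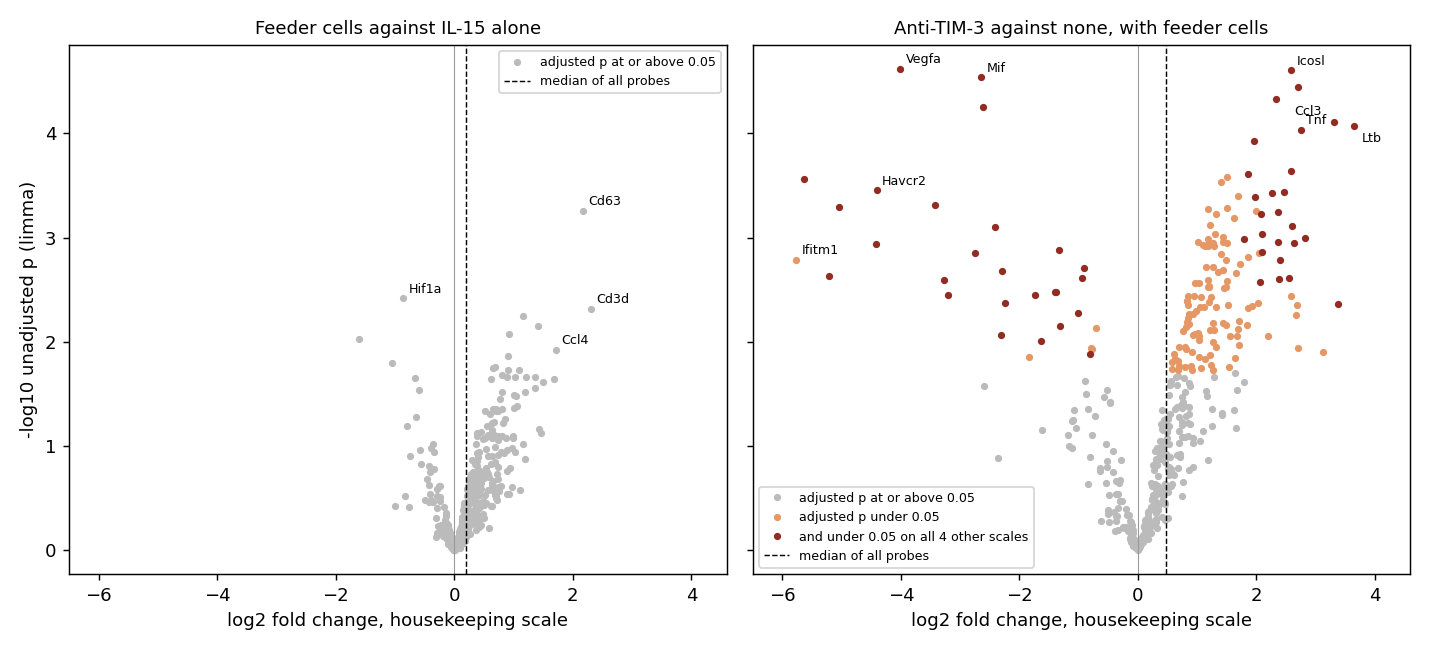
Log2 fold change on the housekeeping scale (horizontal) against -log10 of the unadjusted limma p (vertical) for 430 probes in the feeder and the anti-TIM-3 comparison, with the dashed line at the median of all probes (0.19 and 0.47). No probe passed in the feeder comparison, and 166 passed in the anti-TIM-3 comparison, of which 52 also passed on the 4 other scales.

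Of the 16 tested genes on the list of secreted cytokines and chemokines, 9 rose and 1 fell (10 adjusted over the list alone), and 8 of the rises passed on all scales. Xcl1, encoding lymphotactin, rose by 2.55 ± 0.52 on the log2 scale to a normalised count of 39088. Mif, encoding macrophage migration inhibitory factor, was the gene that fell (-2.64 ± 0.24, limma adjusted p = 0.00382). Ifng, chosen after its values were seen, was at -0.11 ± 0.42 and did not pass. Camera did not separate the list from other genes (adjusted p = 0.467, and 0.950 with an estimated correlation). Without untreated feeder replicate 3 no member of any list passed, and without anti-TIM-3 replicate 2 this list had 5 rises.

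Of 17 tested NF-kB pathway genes, 11 rose and none fell (13 adjusted over the list alone), with 3 rises past the threshold on all scales, 3 without untreated feeder replicate 2 and 3 without anti-TIM-3 replicate 2. Traf3, encoding a signalling adaptor (2.09 ± 0.38), Nfkbia, the inhibitor IkB-alpha (2.08 ± 0.32), Relb, an NF-kB subunit (1.97 ± 0.29), and Ikbke, a kinase gene (1.87 ± 0.35), had the largest log2 fold changes. Nfkbia and Traf3 restrain the pathway, whereas Relb is a transcription factor of it. This was the only list of 17 tested that passed in camera at the preset correlation (adjusted p = 0.0244), and it did not pass with an estimated correlation (adjusted p = 0.950), without IL-15 replicate 1 (adjusted p = 0.0641) or without IL-15 replicate 3 (adjusted p = 0.0690).

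Receptor genes of NK cells went both ways. Of 16 activating receptor and adaptor genes, 8 rose and none fell (9 adjusted over the list alone), among them Klra4, Klrc2, Klrb1c, encoding NK1.1 (2.03 ± 0.46 on the log2 scale), and Hcst, encoding the adaptor DAP10 (1.69 ± 0.25). No rise on this list passed on all scales, and with TMM 1 member rose and 2 fell. Of 6 Ly49 receptor genes, Klra4 rose, Klra2 and Klra5 (-1.40 ± 0.30) fell, and Klra6 was at 1.63 ± 0.65 and did not pass (4 adjusted over the list alone). Of 9 inhibitory receptor genes, 2 rose and 2 fell (5 adjusted over the list alone): Cd160 rose by 2.58 ± 0.34, and Havcr2 and Klrg1 fell. Ctla4 was at -2.60 ± 0.90 with a limma adjusted p of 0.0640. It had 31 and 160 recovered counts in untreated feeder replicates 2 and 3, so that size depends on replicate 3. On the list of TIM-3 ligands and partners, the kinase genes Fyn (1.01 ± 0.18) and Lck (0.80 ± 0.23) rose, Havcr2 fell, and 2 of 5 did not pass (3 adjusted over the list alone). Neither the Fyn nor the Lck rise passed with TMM, where their log2 fold changes were 0.48 and 0.27, nor did that of Klra4, and 1 inhibitory receptor gene rose there. Without untreated feeder replicate 2, and likewise without anti-TIM-3 replicate 2, the rises were 1 activating receptor gene, 1 inhibitory receptor gene, and 0 on each of the other 2 lists.

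Of 8 cytotoxic effector genes, 4 rose and 1 fell (5 adjusted over the list alone). Prf1, the gene of the pore-forming protein perforin, fell by 2.41 ± 0.39 on the log2 scale, from a normalised count of 11568 to 2047. The death ligand genes Tnfsf10 (2.36 ± 0.36) and Fasl (1.35 ± 0.27) rose, as did the cathepsin gene Ctsw, from a normalised count of 1539 to 4393. The granzyme genes Gzma and Gzmb, chosen after their values were seen, were at -0.07 ± 0.29 and -0.30 ± 0.28 and did not pass, at normalised counts of 30789 and 14675 in the anti-TIM-3 libraries. Of 11 apoptosis genes, 4 rose and 2 fell (6 adjusted over the list alone), with Casp1, of inflammatory cell death, at 1.40 ± 0.19. With TMM, 2 cytotoxic effector genes rose and 1 fell, and 2 apoptosis genes rose and 2 fell. With the replicate block, 2 cytotoxic effector genes rose and 0 fell, so the call on Prf1 ended, and 0 apoptosis genes rose or fell. Without untreated feeder replicate 2, and likewise without anti-TIM-3 replicate 2, 1 cytotoxic effector gene rose and 1 fell, and 1 apoptosis gene rose and 0 fell.

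Interferon-stimulated genes had 7 rises and 1 fall among 18 tested (8 adjusted over the list alone). Gbp5, a guanylate-binding protein gene (2.46 ± 0.35 on the log2 scale), Irf1, a transcription factor gene (1.79 ± 0.31), and Zbp1, a nucleic acid sensor gene (1.63 ± 0.26), rose, and Ifitm1 fell. In IL-15 and common gamma chain signalling 6 of 14 genes rose and none fell (6 adjusted over the list alone), led by Il21r (2.32 ± 0.23), the feedback inhibitor gene Socs1 (1.95 ± 0.23) and the shared receptor chain gene Il2rg (1.21 ± 0.20). Il15ra was at 1.25 ± 0.55 and did not pass, with 30 and 10 recovered counts in untreated feeder replicates 2 and 3, so its size depends on replicate 3. Of 13 genes of MHC class I and antigen processing, 6 rose and none fell (6 adjusted over the list alone), with Tapbp at 1.51 ± 0.23, H2-K1 at 1.43 ± 0.28 and H2-D1 at 1.20 ± 0.27. Fewer passed with TMM, where 3 interferon-stimulated genes rose and 1 fell, 3 signalling genes rose, and 2 class I genes rose and 1 fell. On all scales, 2 rises of interferon-stimulated genes, 2 of signalling genes and 0 of class I genes passed. The numbers of rises on these lists, on the housekeeping scale, were 7, 2 and 1 without untreated feeder replicate 2, and 4, 3 and 1 without anti-TIM-3 replicate 2. Camera gave adjusted p-values of 0.467, 0.141 and 0.656 for these 3 lists.

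Of 19 transcription factor genes, 5 rose and 2 fell (7 adjusted over the list alone). Tcf7, encoding TCF-1 (2.20 ± 0.58 on the log2 scale), Tbx21, encoding T-bet (1.44 ± 0.25), and Ets1 (1.28 ± 0.23) rose, and Irf8 fell by 2.61 ± 0.27. Of 13 co-stimulatory and activation genes, 3 rose and 2 fell (5 adjusted over the list alone): the early activation marker gene Cd69 (1.31 ± 0.21) and Cd38 (1.27 ± 0.32) rose, and the transferrin receptor gene Tfrc (-1.63 ± 0.44, and -0.94 without anti-TIM-3 replicate 2) and Icos (-1.38 ± 0.30) fell. Of 19 adhesion and trafficking genes, 5 rose and none fell (5 adjusted over the list alone), with Icam1 at 2.37 ± 0.41, the chemokine receptor gene Cxcr6 at 2.26 ± 0.32 and the integrin gene Itga2 at 1.99 ± 0.31. Cxcr3 was at 1.79 ± 0.60 and did not pass. Its normalised count in the anti-TIM-3 libraries averaged 341 with an SD of 203, so that size is loosely determined. With TMM the balance moved, to 2 rises and 2 falls of transcription factor genes, 1 rise and 4 falls of co-stimulatory genes, and 3 rises and 3 falls of adhesion genes. No rise of a transcription factor or co-stimulatory gene passed on all scales. Without untreated feeder replicate 2, and likewise without anti-TIM-3 replicate 2, 0 transcription factor genes, 1 co-stimulatory gene and 3 adhesion genes rose.

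**Figure D3:**
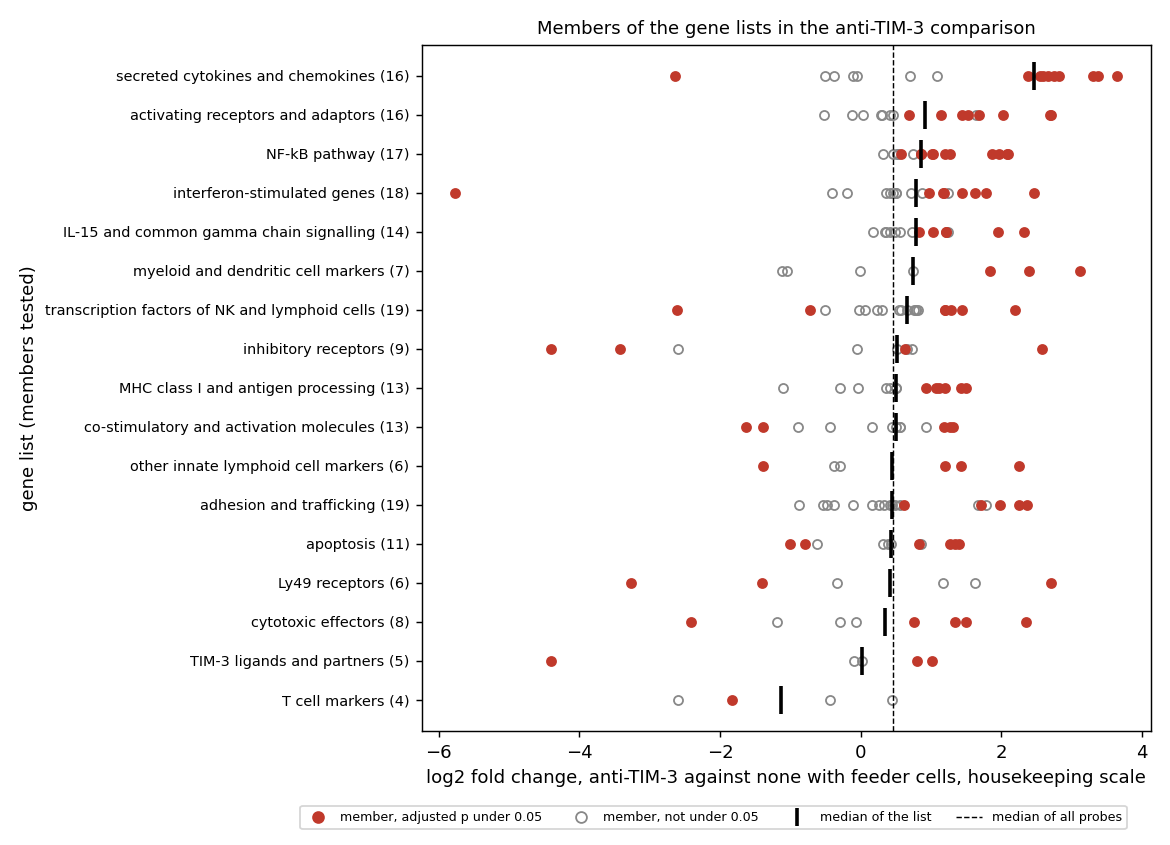
Log2 fold change of each tested member of 17 gene lists in the anti-TIM-3 comparison, with filled points past the adjusted threshold, a bar at each list's median and a dashed line at the median of all probes (0.47). The median of the cytokine and chemokine list was 2.47, and that of the T cell markers was -1.13.

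Markers of other cells moved in different directions. Of 7 tested myeloid and dendritic cell markers, 3 rose and none fell (3 adjusted over the list alone): Cd74, the class II gene H2-Aa (2.39 ± 0.45 on the log2 scale) and H2-Dma (1.84 ± 0.46). The monocyte marker gene Cd14 was at -1.12 ± 0.59 and did not pass. Of 4 T cell markers, Cd3d fell by 1.83 ± 0.54 and the others did not pass (0 adjusted over the list alone). Of 6 markers of other innate lymphoid cells, Cxcr6, Kit (1.43 ± 0.25) and Gata3 (1.20 ± 0.25) rose and Icos fell (4 adjusted over the list alone). The tested B cell marker, Tnfrsf13c, was at 0.13 and did not pass, and of the ligands carried by the feeder line Icam1 was the one tested (1 adjusted over the list alone). With TMM, 1 myeloid marker rose (H2-Aa), 2 T cell markers fell, and 1 marker of other innate lymphoid cells rose (Cxcr6) and 1 fell (Icos); Cd74 and H2-Dma passed on none of the 4 other scales, and Cd3d did not pass with total count. Without anti-TIM-3 replicate 2, 0 myeloid markers rose, 0 T cell markers fell, and 1 marker of other innate lymphoid cells rose.

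The feeder comparison asks what expansion with feeder cells changed in the absence of antibody. No gene passed the threshold in limma with Benjamini-Hochberg adjustment, with 39 of 430 probes at an unadjusted p under 0.05 and 0 calls with voom. The leading values were higher with feeder cells for Cd63, a granule membrane protein gene (2.17 ± 0.33 on the log2 scale, limma adjusted p = 0.237), Cd3d (2.31 ± 0.54), Ccl4 (1.71 ± 0.49), Ccl3 (1.42 ± 0.36), Cd28 (1.16 ± 0.28), Kit (0.93 ± 0.25) and Lag3 (0.90 ± 0.27). They were lower for Ada, encoding adenosine deaminase (-1.61 ± 0.43), and Hif1a (-0.86 ± 0.19). In IL-15 replicates 1 and 3 the recovered counts were 32 and 107 for Ccl4, 68 and 161 for Ccl3, and 27 and 88 for Cd3d. The sizes of these differences therefore depend on IL-15 replicate 1. Havcr2 was at 0.70 ± 0.62 (limma adjusted p = 0.777).

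None of the 19 lists held a gene past the threshold over all genes in the feeder comparison. Of 4 T cell markers, 2 passed adjusted over the list alone, and for each of the other lists that number was 0. No list passed in camera (smallest adjusted p = 0.170, and 0.688 with an estimated correlation). Without IL-15 replicate 3, 7 genes passed, all of them higher with feeder cells. A list passed in camera without IL-15 replicate 3 (smallest adjusted p = 0.00464) and without untreated feeder replicate 3 (smallest adjusted p = 0.0131).

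Feeder cells and anti-TIM-3 together were compared with IL-15 alone. The chemokine genes Ccl3 (4.73 ± 0.36 on the log2 scale), Ccl1 (4.27 ± 0.77) and Ccl4 (4.10 ± 0.49) rose most, with Cd74 (4.23 ± 0.90), Ltb (3.97 ± 0.40), Csf2 (3.82 ± 0.48), Klra4 (3.68 ± 0.76), Cd63 (3.46 ± 0.33), Klrc2 (3.44 ± 0.62) and Tnfsf8 (3.35 ± 0.26). Cma1 (-6.22 ± 1.05), Ctsg (-5.18 ± 0.76), Ifitm1 (-5.18 ± 1.08), Cd55 (-4.63 ± 0.76), Ifitm2 (-4.23 ± 0.78) and Havcr2 (-3.71 ± 0.62) fell most, followed by Klrg1 (-3.47 ± 0.51), Vegfa (-3.26 ± 0.35), Irf8 (-3.02 ± 0.27) and Ctla4 (-2.91 ± 0.90). The sizes and ranks of the Cma1 and Ctsg falls are poorly determined, since both were at or near the negative control level in the anti-TIM-3 libraries. The calls on Ccl1, Ifitm1 and Ifitm2 ended without either IL-15 library (limma adjusted p of 0.0851 to 0.171), with Ifitm1 at -3.35 without anti-TIM-3 replicate 2. Those on Cd74 and Ctla4 ended without IL-15 replicate 1 (limma adjusted p = 0.0655 and 0.128), those on Cd74, Klra4 and Ctla4 without anti-TIM-3 replicate 2 (limma adjusted p = 0.0524, 0.0524 and 0.117), and that on Ctla4 without anti-TIM-3 replicate 1 (limma adjusted p = 0.0877).

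In this comparison 219 of 430 probes passed in limma with Benjamini-Hochberg adjustment, 189 higher and 30 lower, with a median log2 fold change of 0.70. The split was 72 and 77 with TMM, 47 and 47 with positive controls, 74 and 54 with total count, and 80 and 76 with median of ratios. On all scales 42 rises and 29 falls passed, and 14 of the called rises changed sign on at least 1 other scale. Without anti-TIM-3 replicate 2 the count was 113. Interferon-stimulated genes had 14 rises and 1 fall of 18 (5 and 1 with TMM), NF-kB pathway genes 12 rises of 17 (4 with TMM), adhesion genes 10 rises and 1 fall of 19 (4 and 3 with TMM), and activating receptor genes 10 rises and 1 fall of 16 (7 and 1 with TMM). Without anti-TIM-3 replicate 2 the rises on these 4 lists were 7, 5, 3 and 6; interferon-stimulated genes had 9 without anti-TIM-3 replicate 1, and NF-kB pathway genes 7 without IL-15 replicate 1. Camera called no list (smallest adjusted p = 0.314, and 0.912 with an estimated correlation).

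The authors' deposited table of 1 comparison was set against these values. Its log2 fold changes matched those of anti-TIM-3 against untreated feeder libraries, with r = 1.00 across 498 genes and a median absolute difference of 0.0064. The authors' deposited table listed 170 genes at a q-value under 0.05, 141 higher and 29 lower. Of 410 genes tested in both, 163 passed in the authors' deposited table, 165 in the limma fit and 154 in both, all 154 with the same sign.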

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

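The median-of-ratios, voom and plain limma settings were chosen after seeing the data. The list tests with TMM were the planned form, and list tests on the housekeeping scale took their place as the main ones. The deposited values assignable to samples were on a log2 scale. DESeq2 and the planned edgeR fit were not run, although whole counts were recovered for each library. The housekeeping scale of the authors' log2 values became the main setting in place of the planned TMM. For genes changed by anti-TIM-3 (166), the count was 95 with TMM, 69 with positive control scaling, 100 with total count and 102 with median of ratios, and 0 to 171 on leaving out each library. For feeder cells with anti-TIM-3 (219), it was 94 with positive control scaling, 128 with total count, and 113 to 199 on leaving out each library. For feeder cells alone (0), it was 1 with positive control scaling and 0 to 7 on leaving out each library. The scales differ by construction in what they hold constant, and the other causes were not tested. With positive control scaling limma gave a median of 1290 total degrees of freedom against 6.18 in the main setting, so its p-values there may be too small; the cause was not tested. Without that scale, 44 rises and 30 falls under anti-TIM-3 passed on all the remaining scales. Count filters, negative control subtraction, voom, plain limma and the fit of 4 libraries kept all 3 counts within 1.5 times.

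The log2 fold change of Havcr2 lay between -5.34 and -3.48 on leaving out each library. Among named genes that had not passed under anti-TIM-3, Gzma reversed to 0.0398 with the replicate block, with a range of -0.30 to 0.16 on leaving out each library. Ifng reversed to 0.14 with the block (range -0.30 to 0.0867), and H2-Ab1 to 0.59 with the block and 0.016 with voom (range -0.14 to 0.13). The cause was not tested. The NF-kB list was the 1 list past the threshold under anti-TIM-3; the number was 0 to 2 on leaving out each library, 1 with TMM and 0 with an estimated correlation. A library left alone in its group is assumed to vary like the other groups.

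Deviations from the group means of libraries with the same title number correlated at 0.08, 0.04 and -0.41. With 2 libraries per group the deviations of a group mirror each other and mix 2 title numbers. These values therefore do not settle whether equal numbers mark the same animal or batch, and the main fit used no block. The anti-TIM-3 libraries carried title numbers 1 and 2, and the untreated feeder libraries 2 and 3. If the numbers mark animals or batches, a difference between numbers 1 and 3 is part of the anti-TIM-3 fold changes of the main fit. With the replicate block 61 genes passed for anti-TIM-3 (47 rose and 14 fell) and 76 for feeder cells with anti-TIM-3. Under anti-TIM-3 the block left 7 rises and 1 fall of cytokine and chemokine genes, and 3 rises of NF-kB pathway genes. The calls on Prf1, Klra2, Klra5 and Cd3d ended with the block, since no gene of their lists fell there. In simulations of the anti-TIM-3 comparison with 430 probes, 19.8% of 1.5-fold changes were called, so smaller changes were mostly not detectable with 2 libraries per group. In these simulations 200 probes were changed. Detection where few probes change, as may be so for feeder cells alone, was not simulated and can be lower at every fold change.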

Other observations

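All genes in this paragraph were chosen after their values were seen. In the anti-TIM-3 comparison, Icosl, encoding the ligand of ICOS, shared the smallest adjusted p of the comparison and rose by 2.58 ± 0.23 on the log2 scale (limma adjusted p = 0.00382), while Icos itself fell. Tgfbr1, a TGF-beta receptor gene (1.86 ± 0.25), and Smad3, its signal transducer (2.06 ± 0.43), rose. Hif1a, a transcription factor gene of the oxygen response (-0.94 ± 0.19), and Gpi1, a glycolytic enzyme gene (-1.34 ± 0.24), fell with Vegfa and Mif. The adhesion genes Cdh1 (-2.75 ± 0.50) and Epcam (-2.25 ± 0.51) fell as well. All of these calls were past the threshold on the 4 other scales, and none was past it without untreated feeder replicate 3, where limma adjusted p-values were 0.0507 to 0.113 and Icosl was at 2.55. Those of Smad3, Hif1a, Gpi1, Cdh1, Epcam and Icos also ended without anti-TIM-3 replicate 2, and that of Smad3 without untreated feeder replicate 2.

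The labels give an antibody exposure of 4 h. If synthesis stopped at its start, the smallest fall over the 4 library pairs needs a transcript half-life of at most 1.05 h for Ifitm1, 1.02 h for Cd55 and 1.32 h for Havcr2 (0.694 h, 0.793 h and 0.907 h from the mean falls). Of the 31 genes that fell, 8 needed a half-life of at most 1.5 h in all 4 pairs, among them Ctsg, Cma1 and Klra2, whose falls are poorly determined. Transcript half-lives were not measured here.

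All tests in the following paragraphs were chosen after the results were seen.

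Genes that differed under anti-TIM-3 also differed between libraries that had no antibody: across 430 tested probes, the difference between the 2 IL-15 libraries correlated with the anti-TIM-3 log2 fold change at r = 0.445 (Spearman's rho 0.377), although these values share no library, and genes are not independent replicates. Relative to the median, 27 of the 31 genes that fell were lower in IL-15 replicate 3 than in replicate 1, and 88 of the 135 genes that rose were higher. Title number 1 was among the anti-TIM-3 libraries and number 3 among the untreated feeder libraries. A shared effect of the title number alone would thus give a negative r, so the positive r argues against it as the source of this correlation. Noise of dim probes is argued against, since r was 0.574 over 227 probes with a mean of at least 200 counts. Whether the gradient seen between the IL-15 libraries is the whole difference is not settled. Between them 174 probes were level (within 0.25 of the median difference). Of these, 12.6% differed from the median anti-TIM-3 change by over 1 on the log2 scale, against 27.2% of all tested probes. Over the 4 library pairs the share of level probes was 9.77% to 19.5%, with 1 pair under a bound of 10% set at first. Between libraries of a group it was 1.72% and 4.02%. Limma called 63 of the level probes, and 37 with TMM. In all 4 pairs, 13 of the level probes lay over 1 from the median in the same direction, against 69 of all tested probes. The SD of the anti-TIM-3 changes was 1.88 times that of the IL-15 differences. Level probes were picked from 1 library on each side. A stronger form of the same gradient, or noise in that choice, could therefore also give such shares. A gradient between libraries, such as culture state or cell composition, may contribute, and one that the IL-15 libraries do not show stays open.

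Rises far outnumbered falls under anti-TIM-3 on the housekeeping scale (135 and 31), less so with total count (63 and 37) and median of ratios (53 and 49), and not with TMM (44 and 51) or positive controls (32 and 37). A single aberrant housekeeping probe is argued against, since leaving out any 1 moved the fold changes by at most 0.0408 against a median of 0.47. Over the positive controls, the mean difference of the 20 housekeeping probes was -0.51 under anti-TIM-3, with 19 lower and 1 higher. Over the 4 library pairs that mean lay between -1.21 and 0.19. The median of the other probes was at -0.0063, between -0.53 and 0.58 over those pairs. That spread does not tell whether the anti-TIM-3 libraries held less RNA. A loss of RNA shared by all probes would lower housekeeping and panel probes alike and cancel on the housekeeping scale. The excess of rises on that scale stayed after subtraction of the negative control mean (128 and 32, median log2 fold change 0.48). With at least 50 counts in at least 2 libraries it also stayed (134 and 30). Since a shared loss cancels by construction, these 2 settings do not test it. They bear only on background and low counts, and argue against those as the source of the excess. A broad rise of panel genes and a fall of housekeeping transcripts under the antibody stay open and were not tested.

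Cd74, H2-Aa and H2-Dma rose under anti-TIM-3 on the housekeeping scale, and of these H2-Aa alone passed on any of the 4 other scales, on all of them. Carried-over antigen-presenting cells are argued against as the whole source, since H2-Ab1, which encodes the partner chain of H2-Aa, was at -0.01 ± 0.56, and H2-Aa rose by 2.40 more on the log2 scale (1.47 to 3.33 over the 4 library pairs). Cd14 (-1.12 ± 0.59) and Tlr4 (-1.05 ± 0.47) did not pass, whereas Ctss (2.09 ± 0.35) and Itgax (1.71 ± 0.47), which myeloid cells also express, rose, and Itgam was at 1.67 ± 0.59 and did not pass. Against IL-15 alone, H2-Ab1 did rise with feeder cells and anti-TIM-3 (1.68 ± 0.56, limma adjusted p = 0.0463; 0.80 without IL-15 replicate 1, and not past the threshold without any 1 library other than IL-15 replicate 3), which such cells would also give, so a smaller contribution from them stays open. The cells were purified as NK cells before RNA extraction, and expression of these genes by the NK cells themselves is a hypothesis that was not tested further.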
